A study of Homo sapiens with 12 samples.

How the data were processed

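The series measured messenger RNA in EA.hy926 cells, a human endothelial line made by fusing umbilical vein endothelial cells with the lung carcinoma line A549. There were 12 libraries in 4 groups of 3: control, hypoxia, TEPA and TEPA+hypoxia. Per the labels, TEPA (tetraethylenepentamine, a chelator of copper) was added at 50 µM for 16 h and the cells were then kept for a further 8 h at normal oxygen or in 1% oxygen. RNA was extracted with TRIzol, poly(A) RNA was selected, and libraries were made with a directional kit. The authors aligned reads with HISAT2 2.1.0 to the GRCh38 build and named DESeq among their tools. The read counter, the gene annotation and the strand setting are not given in the sources used here.

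The deposited table held raw counts for 51141 gene symbols in the 12 libraries, all whole numbers of at least 0, with 1 column per library. Column totals ran from 13406858 in hypoxia 3 to 24778944 in TEPA 1. CPM are counts scaled by the library total times its TMM factor (the scaling named below). That factor was 0.772 in hypoxia 2, 0.838 in hypoxia 3 and 1.03 to 1.08 in the other libraries. CPM in hypoxia 2 and 3 are therefore higher than scaling by the total alone would give. The floor of 3 counts in a library lay between 0.118 and 0.267 CPM. Floors cover counting error only, while the SE of a log2 fold change comes from the edgeR fit and includes the spread between libraries. Of the symbols, 40269 matched a current RefSeq gene directly and 1992 more through an older symbol. Coordinates are from GENCODE 29 on GRCh38, a copy whose build may not be the annotation the authors counted against. Some well-known genes were listed at or near 0 in all libraries (HK1 had 0 counts in total, CANX 4, TXNRD1 2 and AMD1 2), so a gene listed at 0 was not read as a gene that is silent.

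Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes with low counts were removed with filterByExpr by group, which left 14447 genes holding 99.9% of all counts. Libraries were scaled by TMM, and all 12 libraries were fitted together with 1 mean per group and no covariate. Each gene was tested by the edgeR quasi-likelihood F-test (two-sided), and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were hypoxia against control, TEPA+hypoxia against TEPA, TEPA against control, TEPA+hypoxia against hypoxia, the interaction (the response to hypoxia with TEPA minus the response without it) and the average of the 2 responses to hypoxia. Genes called in the average effect were then tested for an interaction with the adjustment over those genes alone, to count those whose change was smaller with TEPA. The common dispersion was 0.0339, and 0.00850 without hypoxia 2 and 3. The labels do not say whether replicates are separate cultures, so every p-value measures only the spread between these libraries.

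There were 32 gene lists fixed by hand, and 30 with at least 5 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists within a contrast. They covered HIF target genes, glycolysis, components of the HIF pathway, angiogenesis signalling, copper handling, metallothioneins, iron handling, polyamine metabolism, NRF2 targets, cholesterol synthesis, the respiratory chain (nuclear and mitochondrially encoded), histone demethylases, extracellular matrix, autophagy and lysosome, ribosomal proteins, immediate early genes, heat shock proteins, and markers of endothelial, epithelial, fibroblast and mural, and leukocyte cells. Further lists are named where their result is given. All symbols of the lists were found in the table, and 147 of 765 distinct members had too few counts to be tested. Changed members were counted with the adjustment over all genes and with the adjustment over the list alone. Camera with an estimated correlation and fry were run beside the preset.

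The genes named in the text follow a rule. For each of the 4 pairwise contrasts and the interaction, it takes the 6 highest and 6 lowest log2 fold changes among called genes with a coding symbol, a mean of at least 5 CPM and, for pairs of groups, no overlap between libraries. It adds 16 genes of HIF signalling and copper handling, and up to 4 members with the smallest p of each list described. Groups, contrasts, tests, lists, this rule and most alternatives were fixed before the data were examined.

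The alternatives were RLE size factors, upper quartile scaling, no filter, a filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, only the 2 groups compared, and each library left out in turn. After the data were examined, fits were added without hypoxia 2 and 3, with a correction for GC content and transcript length (splines with 4 degrees of freedom per library, 13015 genes, 90.1% of those tested), and with that correction plus the replicate block. For genes and lists the fit of only the 2 groups compared was also added at that point. Without hypoxia 2 and 3, 15195 genes were tested, and the lone hypoxia library was assumed to vary like the other groups.

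The procedure was tested on simulated counts with known changes. With the spread of all 12 libraries, the test of hypoxia against control found 7.46% of changed genes at a fold of 1.5, 68.7% at a fold of 2 and 97.0% at a fold of 4, with 9 unchanged genes called among 14230. For TEPA against control the percentages were 4.48, 65.7 and 97.0, with 1 unchanged gene called, and for the interaction 2.99, 25.4 and 77.3, with 2. With the spread of the libraries without hypoxia 2 and 3, hypoxia against control gave 71.6, 89.6 and 98.5 (19 unchanged genes called), TEPA against control 70.2, 82.1 and 97.0 (8) and the interaction 40.3, 67.2 and 93.9 (11). All 12 libraries were simulated there too. These percentages therefore do not apply to the fit without hypoxia 2 and 3, which holds 1 hypoxia library. In each simulation the rising and the falling list were called and 0 of 20 unchanged lists were. Genes were drawn independently of each other, and the rising and falling lists held only changed genes. The simulation therefore does not show how the list test behaves where genes are correlated. Every library of a gene was also drawn with the same spread. In the data the hypoxia libraries differed more: hypoxia 1 correlated with hypoxia 2 and 3 at 0.939 and 0.955, against at least 0.988 within the other groups. The percentages and the unchanged genes called therefore do not show how the gene test behaves with so uneven a spread.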

Results

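Gene expression was measured by RNA sequencing in EA.hy926 endothelial cells kept with or without the copper chelator TEPA and then at normal or low oxygen. The design has 4 groups of 3 libraries (control, hypoxia, TEPA, TEPA+hypoxia) and asks how a lack of copper changes the transcriptional response to hypoxia, which runs largely through the transcription factor HIF-1. Total counts were 21049891, 16998936 and 16693713 in control 1 to 3, and 15036668, 17648057 and 13406858 in hypoxia 1 to 3. TEPA 1 to 3 had 24778944, 16812088 and 16190579, and TEPA+hypoxia 1 to 3 had 15977762, 16292429 and 17144682.

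Hypoxia 2 and hypoxia 3 stood apart from the other 10 libraries. The first principal component held 76.2% of the variance and scored them at 126 and 105, against 11.8 for hypoxia 1 and -51.6 to -8.95 for the libraries of the other groups. Across genes, hypoxia 1 correlated with them at r = 0.939 and r = 0.955, while libraries of the same group among the other 10 correlated at 0.988 to 0.994 (genes are not independent replicates). Ribosomal protein genes took 9.89% and 8.54% of their counts, against 3.16% to 5.04% elsewhere. The summed epithelial markers reached 18316 and 15694 CPM in them, against 5604 to 7869 CPM elsewhere, and the endothelial markers 8101 and 7495 CPM against 4569 to 5226 CPM. Fibroblast and mural markers were at 52.7 and 58.7 CPM against 85.0 to 110 CPM, and leukocyte markers at 272 and 250.4 CPM against 193 to 231 CPM. Values for hypoxia 1, or from the fit without hypoxia 2 and 3, therefore stand beside many of the results that use the hypoxia group. Across genes, the difference from the control mean correlated with GC content in hypoxia 1 too (Spearman 0.370, against 0.508 and 0.531 in hypoxia 2 and 3). In TEPA+hypoxia 1 to 3 it was at 0.00208, -0.0531 and -0.337, and elsewhere from -0.424 in control 2 to 0.471 in control 3. The fit without hypoxia 2 and 3 is therefore not free of this trend.

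**Figure D1:**
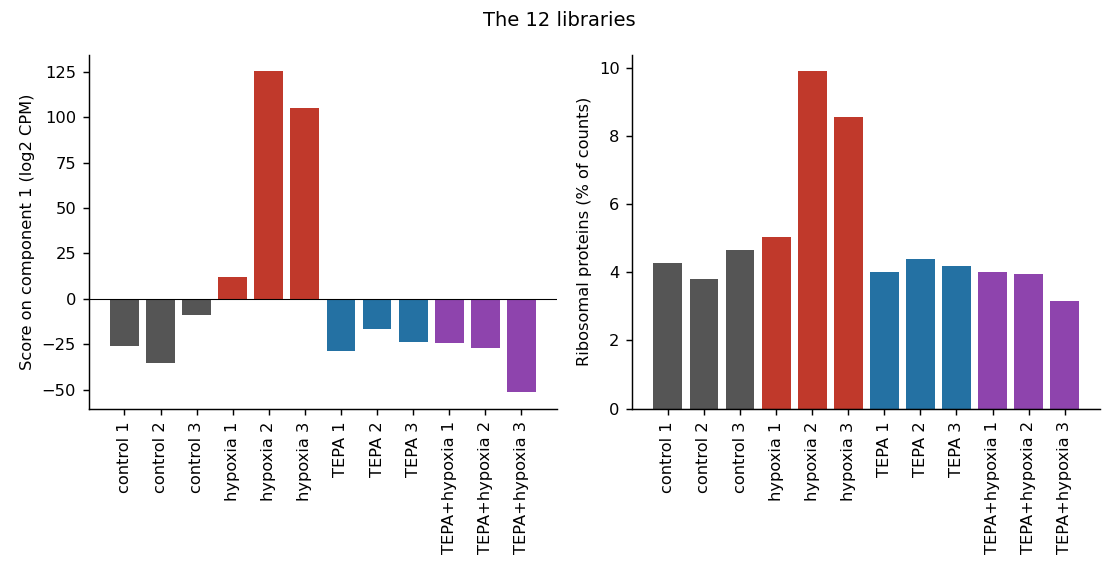
Score of each library on the first principal component of log2 CPM (left) and percent of counts in ribosomal protein genes (right), 1 bar per library, coloured by group. Hypoxia 2 and 3 score 126 and 105 on the component and hold 9.89% and 8.54% ribosomal protein counts, while hypoxia 1 scores 11.8 and holds 5.04%.

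Hypoxia against control asks what 8 h of low oxygen does in cells with normal copper. Well-known targets of HIF-1 rose. ANGPTL4 (chromosome 19, 8363289 to 8374373), a secreted inhibitor of lipoprotein lipase, went from 119 ± 7.61 CPM in control to 905 ± 334 CPM in hypoxia (SD, n = 3 libraries each), a log2 fold change of 2.93 ± 0.24 (SE, adjusted p = 8.4e-04), and stood at 520.3 CPM in hypoxia 1. BNIP3 (chromosome 10, 131966455 to 131982013), a mitophagy receptor, rose from 51.0 ± 1.38 to 90.5 ± 0.695 CPM (log2 0.83 ± 0.08, adjusted p = 0.00221). The vasodilator peptide gene ADM rose by 1.13 ± 0.13 and the glucose transporter gene SLC2A1 by 0.78 ± 0.12. The mTOR inhibitor DDIT4 rose by 1.56 ± 0.20, the enolase ENO2 by 1.04 ± 0.14 and PFKFB4, a regulator of glycolytic flux, by 0.96 ± 0.16. Without hypoxia 2 and 3 the fit holds 1 hypoxia library. Its log2 fold changes were 2.13 for ANGPTL4, 0.81 for BNIP3, 0.94 for ADM and 0.96 for SLC2A1. They were 1.28 for DDIT4, 0.88 for ENO2 and 1.01 for PFKFB4. With only the 6 libraries compared, all 7 genes lost their calls by edgeR (smallest adjusted p of any gene = 0.0582). The correction for GC content and length ended the calls of SLC2A1 (0.30, adjusted p = 0.215) and PFKFB4 (0.46, adjusted p = 0.0756). The smallest rises of the other genes over all other fits were 1.91 for ANGPTL4, 0.77 for BNIP3, 0.49 for ADM, 1.11 for DDIT4 and 0.81 for ENO2.

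Transcripts of the HIF alpha subunits fell in hypoxia. HIF1A (chromosome 14, 61695513 to 61748259) went from 110.2 ± 9.57 to 26.3 ± 26.6 CPM, a log2 change of -2.06 ± 0.52 (adjusted p = 0.00854), and hypoxia 1 alone stood at 56.7 CPM. EPAS1, which encodes HIF-2 alpha, changed by -1.11 ± 0.18 (adjusted p = 0.00601). The values were -0.96 (adjusted p = 0.0327) and -0.71 (adjusted p = 0.0483) without hypoxia 2 and 3. VEGFA, the main vascular growth factor, did not pass the test (log2 0.04 ± 0.20, adjusted p = 0.888; 10.8 CPM in control and 11.01 in hypoxia), nor did the kinase gene PDK1 (adjusted p = 0.900). EGLN3 and IGF2 were listed at 0 in every library, CA9 at 2 counts or fewer, and ATP7A at 8 counts or fewer, and none of the 4 was tested.

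Of 37 measured HIF target genes, 12 rose and 3 fell over all genes, and 10 rose and 2 fell adjusted over the list alone. The list was not called (median log2 0.10, adjusted p = 0.101 with the preset and adjusted p = 0.571 with an estimated correlation), and it was called higher with the correction for GC content and length (adjusted p = 0.00447). When hypoxia 2 and 3 were left out, 9 members rose and 0 fell over all genes, and 14 rose adjusted over the list alone. The list was then called higher (median 0.30, adjusted p = 1.16e-14, and adjusted p = 0.0235 with an estimated correlation). The list of HIF pathway components was not called (2 of 11 rose and 6 fell, adjusted p = 0.121), and it was called lower without hypoxia 2 and 3 (adjusted p = 0.00167, and adjusted p = 0.304 with an estimated correlation). Among them the coactivator genes EP300 and CREBBP changed by -1.51 ± 0.31 and -1.07 ± 0.22, and CITED2, which competes with HIF-1 for these coactivators, by -0.78 ± 0.15, each at an adjusted p of 0.00601. None of these 3 was called without hypoxia 2 and 3 (-0.80, -0.58 and -0.41).

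Ribosomal protein genes rose as a group: 75 of 81 rose and 2 fell over all genes, 76 and 2 adjusted over the list alone, with a median of 1.20 (adjusted p = 2.81e-15). RPS21 and RPL38 rose by 1.84 ± 0.35 and 1.80 ± 0.35, while RPL36A fell from 17.3 ± 1.79 to 5.05 ± 1.04 CPM. The nuclear respiratory chain list rose with 32 of 37 members higher and 1 lower, both over all genes and adjusted over the list alone (median 1.03, adjusted p = 2.15e-07). COX6C and COX5B, subunits of cytochrome c oxidase, rose by 1.42 ± 0.26 and 1.68 ± 0.32, and NDUFS1 of complex I fell by 0.88 on the log2 scale. Glycolysis genes rose (12 higher and 3 lower of 21, 14 and 3 adjusted over the list alone, median 0.58, adjusted p = 0.0166), as did polyamine metabolism (10 and 3 of 16, 13 and 3 adjusted over the list alone, median 0.54, adjusted p = 0.0499), with SMS at 0.51 ± 0.09 and SRM at 1.24 ± 0.26. All 4 list calls were lost with an estimated correlation (adjusted p = 0.571 with an estimated correlation for each). With hypoxia 2 and 3 left out, 0 ribosomal protein genes rose and 1 fell, RPL36A at -1.54 (adjusted p = 0.00778), and 0 nuclear respiratory chain genes passed. Both lists were still called higher at smaller medians of 0.27 and 0.28 (adjusted p = 1.87e-09 and adjusted p = 1.03e-06, and adjusted p = 0.552 with an estimated correlation for each). Glycolysis was called there too (adjusted p = 8.64e-07, and adjusted p = 0.210 with an estimated correlation), but the correction for GC content and length ended its call (adjusted p = 0.206) and those of polyamine metabolism (adjusted p = 0.501) and SRM (0.16, adjusted p = 0.167). The polyamine call was lost without those libraries (adjusted p = 0.127) and in 10 of the 12 fits without 1 library, all except those without hypoxia 1 and hypoxia 2 (adjusted p up to 0.0649, without hypoxia 3).

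Some genes that bind or carry copper rose in the same comparison and others fell. The metallothionein genes MT2A and MT1X, whose products bind copper and zinc, went from 765 to 2622 ± 1510 CPM (log2 1.78 ± 0.35, adjusted p = 0.00601) and from 27.5 ± 2.67 to 88.6 ± 43.8 CPM (1.69 ± 0.30). MT1E rose by 1.56 ± 0.27. In that list 4 members were measured, too few for the list test, and 3 rose and 1 fell, both over all genes and adjusted over the list alone. The copper chaperone genes ATOX1, CCS and COX17 rose by 1.69 ± 0.34, 1.47 ± 0.32 and 1.32 ± 0.27, COMMD1 by 1.16 ± 0.25 and the copper enzyme gene SOD1 by 0.84 ± 0.19. The importer gene SLC31A1 fell by 0.40 on the log2 scale (SE 0.11, adjusted p = 0.0121), a call lost without control 2 (adjusted p = 0.0507) and turned to 0.43 (adjusted p = 0.0198) by the correction for GC content and length. The copper handling list went both ways (7 of 22 rose and 7 fell, adjusted p = 0.959). In hypoxia 1, MT2A stood at 1045 CPM and SOD1 at 295 CPM, and without hypoxia 2 and 3 only MT1E of the 9 genes in this paragraph was called (0.60, adjusted p = 0.0436).

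Other called genes with the largest changes were C4orf48 (2.66 ± 0.53), TYMP (2.45 ± 0.47), CCDC85B (2.32 ± 0.43), TMEM160 (2.28 ± 0.49) and INAFM1 (2.26 ± 0.45) on the higher side. On the lower side they were MBNL1 (-2.96 ± 0.64), CRYBG3 (-2.89 ± 0.73), NCOA3 (-2.88 ± 0.53), HACD2 (-2.82 ± 0.66), ZBED6 (-2.77 ± 0.53) and MTR (-2.71 ± 0.45). None of these 11 was called without hypoxia 2 and 3. The angiogenesis list was not called (adjusted p = 0.393), and it was called higher without hypoxia 2 and 3 (adjusted p = 7.86e-04, and adjusted p = 0.0907 with an estimated correlation). Its members PGF and the VEGF receptor gene KDR changed by 1.43 ± 0.23 and -1.29 ± 0.22, and neither was called without those libraries (0.66 and -0.96, adjusted p = 0.0589 and 0.0681). JUNB, an immediate early gene, rose by 1.48 ± 0.21 and by 1.00 without hypoxia 2 and 3 (adjusted p = 0.0453). TIMP1 rose by 1.47 ± 0.30, the ferritin light chain gene FTL by 1.15 ± 0.25 and JMJD6 by 0.90 ± 0.15, while LAMC1 and KDM5A changed by -0.68 ± 0.14 and -0.79 ± 0.18, none of them called without those libraries, and LAMC1 lost its call with the correction for GC content and length (-0.05, adjusted p = 0.492). In total 4254 genes rose and 4016 fell. The counts were 43 and 35 without hypoxia 2 and 3, of which 41 and 35 were the same genes. With only the 6 libraries compared they were 0 and 0 by edgeR (6939 genes at an unadjusted p under 0.05, smallest adjusted p = 0.0582). On all libraries DESeq2 gave 4404 and 4295 and limma-voom 4052 and 4271. The lower count was 2347 without control 2, 2462 without hypoxia 2 and 2103 without hypoxia 3.

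**Figure D2:**
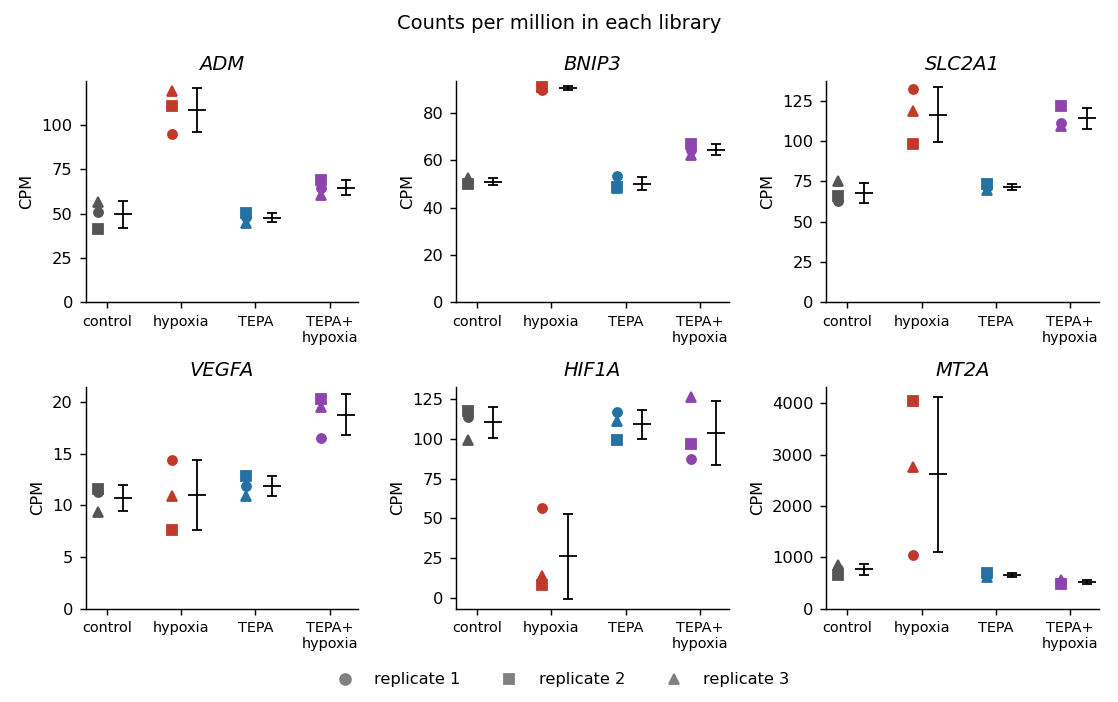
CPM of 6 genes in each library (circle, square and triangle for replicates 1, 2 and 3) by group, with the mean and SD of the 3 libraries as black bars. BNIP3 averages 90.5 CPM in hypoxia and 64.4 CPM in TEPA+hypoxia, ADM 108 and 64.7 CPM, and MT2A is at 1045 CPM in hypoxia 1 against 4055 and 2767 CPM in hypoxia 2 and 3.

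TEPA+hypoxia against TEPA asks what low oxygen does in cells treated with the chelator. The HIF targets ANGPTL4, DDIT4 and ENO2 rose. ANGPTL4 went from 116 ± 9.57 to 341 ± 21.8 CPM (SD, n = 3 libraries each), a log2 change of 1.55 ± 0.23 (adjusted p = 0.0299). DDIT4 went from 7.99 ± 0.811 to 21.8 ± 1.49 CPM (1.44 ± 0.20, adjusted p = 0.0197) and ENO2 by 0.89 ± 0.14 (adjusted p = 0.0403). The splicing kinase gene CLK1 rose by 1.35 ± 0.16 (adjusted p = 0.00722) and the arginine/serine-rich protein gene RSRP1 by 1.20 ± 0.11 (adjusted p = 0.00333). CYP1A1, a monooxygenase induced by the aryl hydrocarbon receptor, fell from 8.08 ± 0.491 to 2.75 ± 0.61 CPM (-1.55 ± 0.20, adjusted p = 0.0129).

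HIF target genes rose as a list: 32 of 37 had a positive log2 fold change, 2 passed over all genes and 13 adjusted over the list alone, with a median of 0.31 (adjusted p = 6.55e-18, and adjusted p = 0.0706 with an estimated correlation). SLC2A1 was at 0.68 ± 0.12 (adjusted p = 0.0824) and VEGFA at 0.66 ± 0.20 (adjusted p = 0.353; 11.9 CPM in TEPA and 18.8 in TEPA+hypoxia). BNIP3 was at 0.36 ± 0.08 (adjusted p = 0.204), ADM at 0.44 ± 0.13 (adjusted p = 0.349). PFKFB4 was at 0.72 ± 0.16 (adjusted p = 0.189) and PDK1 at 0.60 ± 0.21 (adjusted p = 0.504). Hypoxia 2 and 3 enter this comparison only through the shared spread, the scaling and the gene filter. Without them more HIF targets passed, both over all genes and adjusted over the list alone. SLC2A1 (adjusted p = 8.77e-04), VEGFA (0.0141), BNIP3 (0.0225), ADM (0.0467) and PFKFB4 (0.0225) were then among the called genes, and HIF1A was at -0.07 (adjusted p = 0.757). EPAS1 was at -0.50 ± 0.18 (adjusted p = 0.5) and called without those libraries (-0.49, adjusted p = 0.0225).

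Angiogenesis signalling rose (1 of 26 passed over all genes and 4 adjusted over the list alone, median 0.09, adjusted p = 0.00606, adjusted p = 0.156 with an estimated correlation), with APLN, the gene of the vascular peptide apelin, at 0.47 ± 0.11 (adjusted p = 0.204). Glycolysis was called higher (1 of 21 over all genes, 3 adjusted over the list alone, adjusted p = 0.0154, adjusted p = 0.291 with an estimated correlation) although its median was -0.01 and its mean 0.13. That call was lost without TEPA 3 (adjusted p = 0.133), TEPA+hypoxia 1 (0.0648) or TEPA+hypoxia 2 (0.104). Mitochondrially encoded genes fell as a list (0 of 13 over all genes, 4 lower adjusted over the list alone, median -0.13, adjusted p = 8.45e-04, adjusted p = 0.352 with an estimated correlation). ND1 was at -0.53 ± 0.10 (adjusted p = 0.143) and ND6 at -0.40 ± 0.12 (adjusted p = 0.361). Ribosomal proteins (78 of 81 negative, median -0.25, adjusted p = 9.96e-07, 0.628 with an estimated correlation) and the nuclear respiratory chain (36 of 37 negative, median -0.23, adjusted p = 3.79e-05, 0.525 with an estimated correlation) were called lower. So were autophagy and lysosome (20 of 23 negative, median -0.15, adjusted p = 3.03e-04, 0.370 with an estimated correlation), NRF2 targets (16 of 18 negative, median -0.21, adjusted p = 0.00494, 0.291 with an estimated correlation) and cholesterol synthesis (20 of 23 negative, median -0.14, adjusted p = 0.0120, 0.156 with an estimated correlation). No member of these 5 lists passed over all genes by edgeR, and adjusted over the list alone 1 ribosomal protein gene and 1 cholesterol synthesis gene did. RPL36A stood at -0.85 ± 0.16 (adjusted p = 0.113), FDFT1 of cholesterol synthesis at -0.34 ± 0.09 (adjusted p = 0.237) and the lysosomal gene GLA at -0.29 ± 0.10 (adjusted p = 0.482).

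In total 9 genes rose and 5 fell. The others, named after their values were seen, were HNRNPU-AS1, SPACA6P-AS, LINC01355 and LOC105370496 on the higher side and the mitochondrial tRNA genes TRNT, TRND and TRNV and LOC105379045 on the lower side. The counts were 201 and 128 without hypoxia 2 and 3, which included all 14 of these genes, 205 and 150 with only the 6 libraries compared, and 92 and 53 by DESeq2. Leaving out hypoxia 1 gave 153 and 101, TEPA 1 gave 2 and 0, TEPA 2 gave 0 and 0, TEPA 3 gave 5 and 1, and TEPA+hypoxia 1, 2 and 3 gave 5 and 2, 1 and 0, and 3 and 0. The lower count was 3 without any single control library and 9 without hypoxia 2. ANGPTL4, DDIT4 and ENO2 lost their calls with the replicate block (adjusted p = 0.113, 0.084 and 0.202). RSRP1 lost its call without TEPA 2 (adjusted p = 0.0665) and with the correction for GC content and length (adjusted p = 0.081), and of the 12 fits without 1 library ANGPTL4 was called in 3, DDIT4 in 5, ENO2 in 2, CLK1 in 8 and CYP1A1 in 7.

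**Figure D3:**
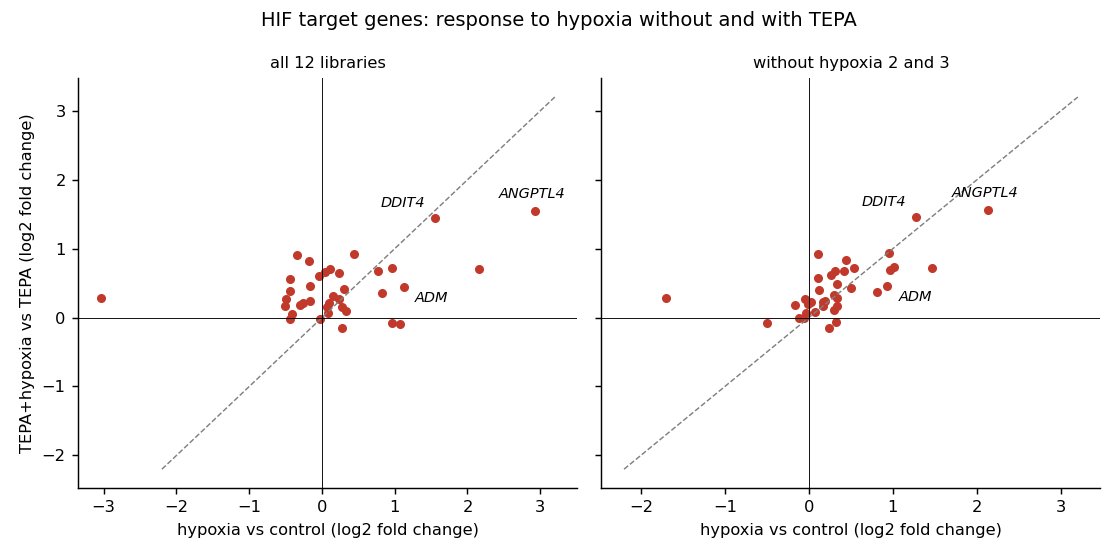
Log2 fold changes of the 37 measured HIF target genes for hypoxia against control (horizontal) and TEPA+hypoxia against TEPA (vertical), 1 point per gene, with all 12 libraries (left) and without hypoxia 2 and 3 (right); the dashed line marks equal changes. Across these genes r is 0.43 on the left and 0.67 on the right, against -0.18 and -0.016 across all genes, and ANGPTL4 is highest on both axes, at 2.93 and 1.55 on the left.

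TEPA against control asks what the chelator does at normal oxygen. Targets of NRF2, the transcription factor of the antioxidant response, fell as a list, and so did genes of cholesterol synthesis. Of 18 measured NRF2 targets 16 had a negative log2 fold change (median -0.22, adjusted p = 2.69e-12, adjusted p = 0.0212 with an estimated correlation). HMOX1 (chromosome 22, 35380361 to 35394214), which encodes heme oxygenase 1, stood at 41.3 ± 6.71 CPM in control and 21.99 ± 2.15 CPM in TEPA (SD, n = 3 libraries each), a log2 difference of -0.91 ± 0.17 (adjusted p = 0.914). The cystine transporter gene SLC7A11 was at -0.80 ± 0.28, the malic enzyme gene ME1 at -0.43 ± 0.17 and PGD of the pentose phosphate pathway at -0.24 ± 0.11, each at an adjusted p of 1. Of 23 cholesterol synthesis genes 18 were negative (median -0.12, adjusted p = 1.06e-04, adjusted p = 0.0212 with an estimated correlation), with CYP51A1 at -0.38 ± 0.17, MSMO1 at -0.28 ± 0.10 and FDFT1 at -0.26 ± 0.09 (adjusted p = 1 for each).

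**Figure D4:**
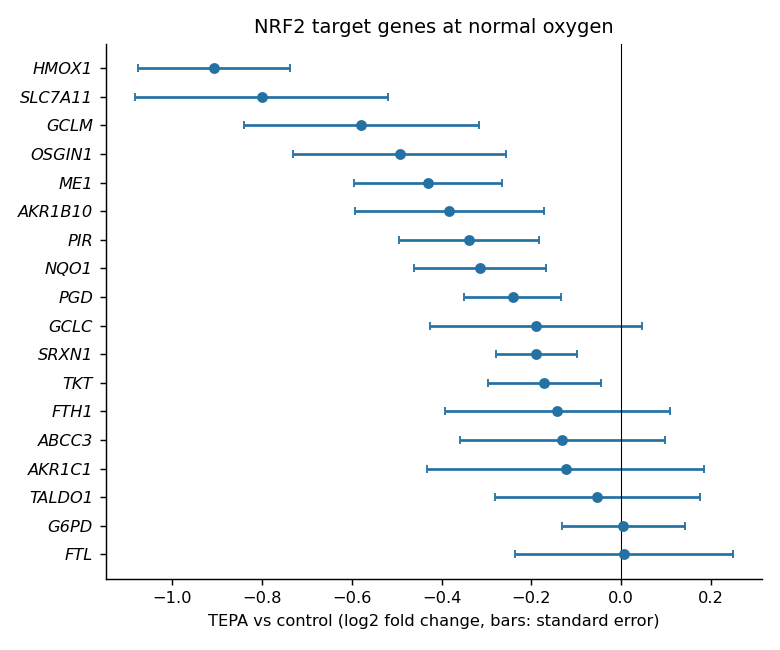
Log2 fold changes of the 18 measured NRF2 target genes for TEPA against control, 1 point per gene with its standard error from edgeR. HMOX1 is lowest at -0.91 and SLC7A11 follows at -0.80, and 16 of the 18 points lie below 0.

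The fixed genes of copper handling and HIF signalling did not pass the test. MT1X was at -0.52 ± 0.30 (27.5 CPM in control and 19.2 CPM in TEPA), MT2A at -0.22 ± 0.34, SLC31A1 at -0.07 ± 0.11, CCS at 0.14 ± 0.32 and SOD1 at -0.10 ± 0.18. HIF1A was at -0.02 ± 0.50, VEGFA at 0.14 ± 0.20, BNIP3 at -0.03 ± 0.08 and SLC2A1 at 0.07 ± 0.12 (adjusted p = 1 for each of these 9 genes). MT1E was at 35.3 ± 2.73 CPM in control and 20.6 ± 0.595 CPM in TEPA (-0.78 ± 0.27, adjusted p = 1). The HIF target list was not called (median -0.01, adjusted p = 0.791), nor were copper handling (14 positive and 8 negative of 22, adjusted p = 0.791) or polyamine metabolism (adjusted p = 0.892).

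By edgeR on all 12 libraries 0 genes rose and 0 fell (289 at an unadjusted p under 0.05, smallest adjusted p = 0.854), against 1 and 5 by DESeq2 and 0 and 0 by limma-voom. In the NRF2 list 0 members passed over all genes and 1 adjusted over the list alone (lower), and 0 of the cholesterol genes passed either way. With only the 6 libraries compared, 2 genes rose and 5 fell, among them MT1E (-0.78, adjusted p = 0.0105) and HMOX1 (-0.91, adjusted p = 0.0137), which were also called lower without hypoxia 2 and 3 (adjusted p = 0.00596 and adjusted p = 0.0389, 0 genes higher and 4 lower). Without hypoxia 1 alone the counts were 1 and 4.

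TEPA+hypoxia against hypoxia asks what the chelator does at low oxygen. Several hypoxia-induced HIF targets were lower with TEPA: ANGPTL4 by -1.41 ± 0.23 (905 ± 334 against 341 ± 21.8 CPM, n = 3 libraries each) and ADM by -0.74 ± 0.13 (108 ± 12.4 against 64.7 ± 4.36 CPM). So were BNIP3, by -0.49 ± 0.08 (90.5 ± 0.695 against 64.4 ± 2.26 CPM), and FAM162A, by -1.14 ± 0.21, all 4 genes at an adjusted p of 0.00217. These 4 were also called lower without hypoxia 2 and 3, at -0.60, -0.55, -0.47 and -0.50. With the correction for GC content and length ANGPTL4 was at only -0.31 (adjusted p = 0.00857) and ADM was not called (-0.02, adjusted p = 0.870). The metallothionein genes were lower as well, MT2A by -2.32 ± 0.36, MT1X by -2.15 ± 0.31 and MT1E by -2.32 ± 0.28, and without hypoxia 2 and 3 by -0.99, -1.01 and -1.35 (adjusted p = 0.00679, 0.00679 and 2.25e-04). HIF1A was higher with TEPA (1.97 ± 0.52, adjusted p = 0.00770, and 0.87 without hypoxia 2 and 3, adjusted p = 0.0183), as was EPAS1 (0.83 ± 0.18, adjusted p = 0.00298, and 0.45 without those libraries, adjusted p = 0.0476).

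VEGFA was higher with TEPA (0.77 ± 0.20, adjusted p = 0.00747) but not called without hypoxia 2 and 3 (0.39, adjusted p = 0.131). SLC2A1 did not pass (-0.03 ± 0.12, adjusted p = 0.838) and was called higher after the correction for GC content and length (0.54, adjusted p = 0.0327). PDK1 and SLC31A1 did not pass (adjusted p = 0.0764 and adjusted p = 0.0785), the latter at 0.24 ± 0.11 and called lower after that correction (-0.68, adjusted p = 0.00262). SOD1 was lower by -1.03 ± 0.19 and CCS by -1.49 ± 0.32 (adjusted p = 0.00217 and adjusted p = 0.00325), and without hypoxia 2 and 3 SOD1 was called (-0.43) and CCS was not (-0.32). ATOX1 and COMMD1 were lower by -1.92 ± 0.35 and -1.60 ± 0.25 and kept their calls there (-0.64 and -0.86). The HIF target list went both ways, with 12 of 37 higher and 7 lower (11 and 7 adjusted over the list alone, adjusted p = 0.716).

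NRF2 targets were lower at low oxygen too, with 12 of 18 lower and 2 higher (the same numbers adjusted over the list alone, median -0.77, adjusted p = 0.00483, adjusted p = 0.723 with an estimated correlation). NQO1 was lower by -0.93 ± 0.15, PIR by -1.08 ± 0.16, PGD by -0.68 ± 0.11 and FTL by -1.51 ± 0.25. In the fit without hypoxia 2 and 3, 8 members were lower and 0 higher, with these 4 genes at -0.49, -0.63, -0.39 and -0.65. Ribosomal proteins were lower (76 lower and 2 higher of 81, 77 and 2 adjusted over the list alone, median -1.45, adjusted p = 5.35e-20), as was the nuclear respiratory chain (32 and 1 of 37 either way, median -1.23, adjusted p = 1.25e-10). So were autophagy and lysosome (16 and 2 of 23, 17 and 2 adjusted over the list alone, median -0.52, adjusted p = 0.00483) and polyamine metabolism (12 and 2 of 16 either way, median -0.81, adjusted p = 0.0153). Among their members RPS21 was at -2.19 ± 0.36, NDUFA1 at -1.91 ± 0.28, cathepsin D (CTSD) at -1.14 ± 0.22, the spermine oxidase gene SMOX at -1.02 ± 0.15 and OAZ1 at -1.35 ± 0.25. Over the other fits these shrank to as little as -0.94, -1.01, -0.26, -0.50 and -0.465, in that order. Extracellular matrix genes were higher (17 higher and 4 lower of 33 either way, median 0.39, adjusted p = 0.0314), with HSPG2 at 0.86 ± 0.12 and COL5A1 at 1.46 ± 0.22 against TIMP1 at -1.68 ± 0.30. The smallest sizes of these 3 over the other fits were 0.73, 1.01 and -0.60. Histone demethylases were higher (11 and 2 of 17, 12 and 2 adjusted over the list alone, median 0.65, adjusted p = 0.0314), with KDM5A at 1.04 ± 0.18 and JMJD1C at 1.77 ± 0.37 against JMJD6 at -0.87 ± 0.15. Here the smallest sizes over the other fits were 0.67, 0.72 and -0.415. All 7 list calls were lost with an estimated correlation (adjusted p = 0.723 with an estimated correlation for each). These calls were made again without hypoxia 2 and 3, but hypoxia 1, the library left there, leans to high GC content as well (Spearman 0.370). The correction for GC content and length ended those of autophagy and polyamine metabolism (adjusted p = 0.325 for each) and histone demethylases (adjusted p = 0.190).

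Other called genes with the largest changes were CRYBG3 (3.89 ± 0.72), MBNL1 (3.24 ± 0.64), MIB1 (3.195 ± 0.57), MTR (3.18 ± 0.45), ZBED6 (3.18 ± 0.53) and NCOA3 (3.14 ± 0.53) on the higher side. Lower were C4orf48 (-3.05 ± 0.54), TYMP (-2.79 ± 0.48), ROMO1 (-2.68 ± 0.41), TMEM160 (-2.53 ± 0.50), ATP5I (-2.46 ± 0.38) and METRN (-2.42 ± 0.39). All but TMEM160 of these 12 were called without hypoxia 2 and 3. In total 4467 genes were higher and 4420 lower. They were 1213 and 1090 without hypoxia 2 and 3, of which 1187 and 1078 were the same genes, and with only the 6 libraries compared 2204 and 2995.

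The interaction asks whether TEPA changes the response to hypoxia. The response was smaller with TEPA for ANGPTL4 (interaction -1.37 ± 0.32), BNIP3 (-0.46 ± 0.12) and ADM (-0.69 ± 0.18). With the correction for GC content and length ANGPTL4 shrank to -0.22 (adjusted p = 0.152) and ADM turned to 0.057 (adjusted p = 0.794), neither called. It was also smaller for MT2A (-2.11 ± 0.49), MT1X (-1.63 ± 0.42) and MT1E (-1.54 ± 0.39), each of the 6 genes at an adjusted p of 0.0236. CCS (-1.63 ± 0.45, adjusted p = 0.0243), SOD1 (-0.93 ± 0.26, adjusted p = 0.0247), ATOX1 (-2.10 ± 0.48) and COMMD1 (-1.64 ± 0.35) went the same way, while HIF1A (1.98 ± 0.71, adjusted p = 0.0464), EP300 (1.71 ± 0.43) and CREBBP (1.24 ± 0.31) had positive interactions. That correction also ended the calls of CCS (-0.55, adjusted p = 0.0878) and HIF1A (1.21, adjusted p = 0.0614). Of the 12 fits without 1 library, 7 called these genes, except that 6 called CCS, 5 SOD1 and 1 HIF1A, and BNIP3 was not called with no filter (adjusted p = 0.117). The smallest sizes over the other fits were -0.49 for MT1X, -0.57 for MT1E, -0.45 for CCS and -0.32 for SOD1. They were -0.81 for ATOX1, -0.89 for COMMD1, 1.01 for EP300 and 0.76 for CREBBP. SLC2A1 did not pass the test (-0.10 ± 0.17, adjusted p = 0.631), nor did VEGFA (0.63 ± 0.29, adjusted p = 0.0938), EPAS1 (0.61 ± 0.25, adjusted p = 0.0696), PDK1 (adjusted p = 0.108) or SLC31A1 (0.31 ± 0.16, adjusted p = 0.126). After the correction for GC content and length VEGFA was called at 1.41 (adjusted p = 0.0447) and SLC31A1 at -0.635 (adjusted p = 0.0355). Without hypoxia 2 and 3 the interactions were -0.56 for ANGPTL4 (adjusted p = 0.0654), -0.44 for BNIP3 (adjusted p = 0.0758), -0.48 for ADM (adjusted p = 0.117), -0.76 for MT2A (adjusted p = 0.0643) and 0.89 for HIF1A (adjusted p = 0.0654).

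The HIF target list showed no interaction as a group (24 of 37 positive, 5 and 5 passing over all genes, 3 and 5 adjusted over the list alone, median 0.16, adjusted p = 0.621). Ribosomal proteins had negative interactions (73 of 81, 75 adjusted over the list alone, median -1.41, adjusted p = 1.55e-18), with RPL38 at -2.31 ± 0.49. So did the nuclear respiratory chain (32 of 37 either way, median -1.26, adjusted p = 8.28e-10), with NDUFA1 at -1.94 ± 0.39 and COX6C at -1.78 ± 0.37. Autophagy and lysosome (9 of 23, 11 adjusted over the list alone, median -0.37, adjusted p = 0.0178), with GLA at -0.65 ± 0.14, and polyamine metabolism (9 of 16, 10 adjusted over the list alone, median -0.71, adjusted p = 0.0222), with OAZ1 at -1.44 ± 0.35, were called lower. All 4 calls were lost with an estimated correlation (adjusted p = 0.802 with an estimated correlation for each). The first 2 lists were called without hypoxia 2 and 3 (medians -0.51 and -0.48) and the others were not (adjusted p = 0.0514 and adjusted p = 0.0588), nor with the correction for GC content and length (adjusted p = 0.458 and adjusted p = 0.452).

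The highest interactions were those of CRYBG3 (3.62 ± 0.93), ZBED6 (3.31 ± 0.68), MBNL1 (3.24 ± 0.83), WWC2 (3.22 ± 0.61), MIB1 (3.196 ± 0.74) and NCOA3 (3.19 ± 0.69). The lowest were those of C4orf48 (-3.09 ± 0.73), ROMO1 (-2.91 ± 0.55), TYMP (-2.75 ± 0.68), CCDC85B (-2.60 ± 0.60), ATP5I (-2.53 ± 0.52) and CRIP1 (-2.50 ± 0.57). In total 2498 genes had a positive and 3113 a negative interaction, all at adjusted p values between 0.0236 and the threshold. By edgeR 0 and 0 genes were called without hypoxia 2 and 3 (4117 at an unadjusted p under 0.05), and 0 and 0 without any single one of control 1, control 2, hypoxia 3, TEPA 2 or TEPA+hypoxia 3. The counts were 5261 and 4497 without hypoxia 1, 834 and 1430 without hypoxia 2, 1168 and 2045 without TEPA 1, and 833 and 1864 without TEPA 3, and the positive count was 1450 without TEPA+hypoxia 2. DESeq2 gave 3115 and 3534 and limma-voom 3277 and 2905.

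The average effect is the mean of the responses with and without TEPA, and these can differ in direction. HIF target genes rose (9 of 37 over all genes, 14 adjusted over the list alone, median 0.23, adjusted p = 6.29e-08), as did glycolysis (4 of 21, 14 higher and 3 lower adjusted over the list alone, adjusted p = 2.37e-04). Immediate early genes (3 of 16, 8 and 1 adjusted over the list alone, adjusted p = 0.0174), heat shock proteins (3 of 14, 6 adjusted over the list alone, adjusted p = 0.0462) and angiogenesis signalling (5 higher and 1 lower of 26, 7 and 4 adjusted over the list alone, adjusted p = 0.0477) rose too. Ribosomal proteins (0 higher and 1 lower of 81, 41 and 2 adjusted over the list alone, adjusted p = 7.6e-09) and the nuclear respiratory chain (0 and 1 of 37 either way, adjusted p = 6.44e-04) were called higher with all libraries and not without hypoxia 2 and 3 (adjusted p = 0.699 and adjusted p = 0.648), and their medians were negative for TEPA+hypoxia against TEPA. Lower were mitochondrially encoded genes (2 of 13, 8 adjusted over the list alone, adjusted p = 0.00153), iron handling (2 of 18, 7 adjusted over the list alone, adjusted p = 0.0174), HIF pathway components (2 of 11, 6 adjusted over the list alone, adjusted p = 0.0182) and cholesterol synthesis (5 of 23, 10 lower and 1 higher adjusted over the list alone, adjusted p = 0.0420). All 11 calls were lost with an estimated correlation (adjusted p = 0.197 with an estimated correlation, or higher). The HIF target list had an adjusted p of 0.00120 with an estimated correlation once hypoxia 2 and 3 were left out.

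Over all genes 451 rose and 249 fell in the average effect, and 184 and 127 without hypoxia 2 and 3, of which 142 and 93 were the same genes. Among the 451 that rose, 160 rose significantly less with TEPA, adjusted over these genes, and 5 rose more. Among the 249 that fell, 121 fell less with TEPA and 5 fell more. The hypoxia group enters both the average effect and the interaction, with opposite signs. Where its libraries spread more than the others, genes chosen as raised lean to a negative interaction and genes chosen as lowered to a positive one. Part of the imbalance in these counts can therefore come from the choice of genes, and how much was not tested. Of the genes called without hypoxia 2 and 3, 8 of 184 rose less and 24 of 127 fell less. All 4 counts moved by over 1.5 times without any single library: they were 4359, 4779, 3559 and 4268 without hypoxia 1, and no higher than 244, 150, 32 and 75 without any other. The correction for GC content and length ended the calls of immediate early genes (adjusted p = 0.317) and HIF pathway components (adjusted p = 0.0932). The immediate early call was also lost without hypoxia 1 (adjusted p = 0.0512), and cholesterol without control 1, hypoxia 1 or TEPA+hypoxia 3 (adjusted p up to 0.0865). Heat shock was lost without control 3, hypoxia 1, TEPA 2, TEPA 3, TEPA+hypoxia 1 or TEPA+hypoxia 3 (adjusted p up to 0.0725). Angiogenesis was lost without control 1, control 3, hypoxia 1, TEPA 2, TEPA 3 or TEPA+hypoxia 3 (up to 0.194).

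Marker lists of cell types were called in no contrast. For hypoxia against control, adjusted p was 0.798 for endothelial markers, 0.426 for epithelial markers and 0.982 for fibroblast and mural markers. Of the leukocyte markers 3 were measured, too few for the list test, and 1 of them rose over all genes and 2 rose and 1 fell adjusted over the list alone. Lists of zinc transporters, the integrated stress response, the unfolded protein response, p53 targets, proliferation, DNA repair, inflammatory signalling, the interferon response, ribosome biogenesis and replication-dependent histones were also called in none of the 6 contrasts with all 12 libraries, at adjusted p values of 0.0833 or more. Without hypoxia 2 and 3, 13 lists in place of 4 were called for hypoxia against control at the preset correlation. Among them were the unfolded protein response on the higher side and DNA repair on the lower. That fit holds 1 hypoxia library, and with all 12 libraries 0 lists were called with an estimated correlation.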

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

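The tests of GC content and length, depth, swaps, single libraries, cell types and of hypoxia 2 and 3 alone were chosen only after the results were seen, and the splits of the samples before.

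The response to hypoxia differed with and without TEPA by the test of the interaction itself, and was smaller with TEPA for the HIF targets BNIP3 (-0.46) and ADM (-0.69), the metallothionein genes MT2A (-2.11) and MT1X (-1.63) and the copper chaperone and enzyme genes CCS (-1.63) and SOD1 (-0.93), and HIF1A fell less (1.98). Of the 12 fits without 1 library, 7 called BNIP3, ADM, MT2A and MT1X, 6 CCS, 5 SOD1 and 1 HIF1A, BNIP3 was not called with no filter (adjusted p = 0.117), and the correction for GC content and length ended the calls of ADM (0.057, adjusted p = 0.794), CCS (-0.55, adjusted p = 0.0878), HIF1A (1.21, adjusted p = 0.0614) and the autophagy and polyamine lists (adjusted p = 0.458 and 0.452). Hypoxia-raised and hypoxia-lowered genes were chosen by the average effect, which shares the widely spread hypoxia group with the interaction. That choice can by itself tilt their counts toward smaller changes with TEPA. In all, 2498 genes had a positive and 3113 a negative interaction, 160 hypoxia-raised genes rose less and 121 hypoxia-lowered genes fell less with TEPA. Over the fits without 1 library these were 0 to 5261, 0 to 4497, 0 to 3559 and 3 to 4268, and the last 2 were 8 and 24 without hypoxia 2 and 3, and 14 and 5 with the replicate block. The lists of ribosomal proteins (adjusted p = 1.55e-18), the nuclear respiratory chain (8.28e-10), autophagy and lysosome (0.0178) and polyamine metabolism (0.0222) differed in the same test, each with a negative median, and none was called with an estimated correlation (adjusted p = 0.802 each), nor the last 2 without hypoxia 2 and 3 (adjusted p = 0.0514 and 0.0588).

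Hypoxia 2 and 3 alone are a candidate source of the interaction's size, and this cannot be told apart from a smaller response with TEPA. Without them, the median interaction of the 5611 genes, each taken in its original direction, was 0.460 times as large, in a fit that shares 10 of the 12 libraries with the first. That fit holds 1 hypoxia library, and 0 genes passed the test in it by edgeR (4117 at an unadjusted p under 0.05; all libraries gave 3115 and 3534 by DESeq2). After the correction for GC content and length the ratio was 0.516 over 5330 genes, just above the bound of 0.5 set for excluding that trend as the cause (a ratio under 0.25 was to show it as the cause). Both bounds were set after the results were seen, and the genes were chosen by their interaction in these same libraries. The ratio therefore excludes nothing, and that trend stays open as a source of part of the interaction's size.

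Hypoxia 2 and 3 lay far from the other 10 libraries. Splines of GC content and length left 65.6% of their variance across genes, which argues against that trend as the whole cause. The larger of the 2 had 17648057 counts, above the 15036668 of the smallest of the other 10, which argues against low depth. Their highest correlation with a library of another group was 0.937, below the 0.988 found within groups among the other 10, which argues against a swap of these 2 libraries inside the series. They correlated with each other at 0.984. Hypoxia 1 was not put to this test. Its highest correlation with a library of another group was 0.988, against 0.939 and 0.955 with hypoxia 2 and 3, so a swap of hypoxia 1 is not addressed. A sample from outside the series and a difference in RNA quality stay open, and no biological explanation was tested.

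The list of NRF2 targets was called lower with TEPA at normal oxygen. The list kept its call after the correction for GC content and length (adjusted p = 7.8e-23), and its highest adjusted p over the 12 fits without 1 library was 1.99e-07. Both argue against these as the whole cause. Chance was not excluded: 5 of 10 splits of TEPA and control, the real one included, called as many lists as the real 2, and another called 5. Those splits counted lists and did not follow the NRF2 list itself. The median of the 9 epithelial markers was 0.0415 (bootstrap SE 0.16, from redrawing genes and not libraries) against -0.22 for the NRF2 targets. Fewer cells of epithelial type cannot be told apart from lower expression this way, since that spread covers the size of the change. The summed epithelial markers were at 7069, 7575 and 7274 CPM in TEPA 1 to 3, and 6580, 5604 and 7397 CPM in control 1 to 3. The series used 1 hybrid line, and AKR1B10 was placed in both lists.

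Splits of the samples into other groups of the same sizes were counted for each contrast. The interaction gave 5611 genes and another of its 31 splits 5896, and the average effect gave 700 and another of its splits 5378, so that chance cannot be excluded for these counts. The highest counts came from splits that put hypoxia 2 and 3 in the same group, and splits that parted them called 0 genes by edgeR, which points to a structure of the samples. The real split was among 2 of 31 with as many genes for the interaction and 4 of 31 for the average effect. For the genes that changed less with TEPA the counts were 160 against at most 102 in another split and 121 against at most 98 (1 of 31 splits each). Splits that parted hypoxia 2 and 3 gave 0 of these genes, so that only the 14 others with both in the same group could compete, and chance stays open. The lists of the average effect numbered 11 against at most 9 (1 of 31 splits), which argues against chance for that count at the preset correlation alone: with an estimated correlation 0 were called, and without hypoxia 1 the calls of 4 were lost. For the lists of the interaction (4 against 8, 15 of 31 splits) it cannot. The pairs of groups have 10 splits, too few for a share under 0.05. Real and highest other counts were 8270 and 3291 genes for hypoxia against control, 14 and 0 for TEPA+hypoxia against TEPA, 0 and 0 for TEPA against control (10 of 10 splits) and 8887 and 0 for TEPA+hypoxia against hypoxia. For lists they were 4 and 5 (7 of 10 splits), 9 and 5, 2 and 5 (5 of 10) and 7 and 6.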

How the results depend on the processing

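The fits without hypoxia 2 and 3, with the correction for GC content and length, with that correction and the block, and the 2-group fits of genes and lists were chosen only after the data were seen. Where a value below moved, the cause was not tested, except that fewer libraries or genes enter some fits.

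RLE and upper quartile scaling and the filter on CPM moved no count of genes by over 1.5 times. A gene or list result counted as reversed when its sign changed and the main or the other fit called it. Sign changes between fits without a call were not counted, such as VEGFA for hypoxia against control (-0.622 to 0.422). Among single genes, 222 of 227 results never reversed in this sense. Over 4942 comparisons 4423 stayed on their side of the threshold, 453 were weaker, 61 stronger and 5 reversed. All 5 reversals came with the correction for GC content and length: ADM in the interaction (0.057, adjusted p = 0.794), SLC2A1 for TEPA+hypoxia against hypoxia (0.54), and SLC31A1 for hypoxia against control (0.43), for TEPA+hypoxia against hypoxia (-0.68) and in the interaction (-0.64); the cause was not tested. ADM stood at -0.69 ± 0.18 before that correction. Of 180 list results none reversed in 3712 comparisons, of which 3498 kept their side, 96 were weaker and 118 stronger. Camera called 37 lists over the 6 contrasts, 2 with an estimated correlation and 72 by fry.

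Without hypoxia 2 and 3, hypoxia against control gave 43 genes higher and 35 lower, TEPA+hypoxia against TEPA 201 and 128, TEPA against control 4 lower, TEPA+hypoxia against hypoxia 1213 and 1090, the interaction 0 and 0, and the average effect 184 and 127, with 8 and 24 genes changing less with TEPA. With only the 2 groups compared, hypoxia against control gave 0 and 0 by edgeR (6939 at an unadjusted p under 0.05), TEPA+hypoxia against TEPA 205 and 150, TEPA against control 2 and 5, and TEPA+hypoxia against hypoxia 2204 higher. DESeq2 gave 92 and 53 for TEPA+hypoxia against TEPA, 1 and 5 for TEPA against control, 1774 and 1610 for the average effect, and 1137 and 1070 genes changing less. Limma-voom gave 3 lower for TEPA+hypoxia against TEPA, 754 lower in the average effect, and 88 and 573 genes changing less. With no filter the average effect gave 723 and 564, with 473 and 457 changing less.

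The replicate block gave 3 lower for TEPA+hypoxia against TEPA, 55 and 24 in the average effect, and 14 and 5 changing less. The replicate numbers do not pair: 18 pairs of libraries with the same number correlated at -0.36 to 0.32 after removal of group means, others at -0.46 to 0.49, and 2 of 12 libraries correlated best with their own number. The correction for GC content and length gave 2 lower for TEPA+hypoxia against TEPA, 1443 and 1994 in the interaction, 693 and 564 in the average effect, and 250.0 and 254 changing less. With the block too, these were 5 higher and 1 lower, 697 and 940, 240.0 and 149, and 38 and 52.

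Without 1 library, hypoxia against control gave 2853 to 5085 genes higher and 2103 to 5538 lower, TEPA+hypoxia against TEPA 0 to 153 and 0 to 101, TEPA against control 0 to 1 and 0 to 4, and TEPA+hypoxia against hypoxia 3133 to 5765 and 3487 to 5100. The interaction gave 0 to 5261 and 0 to 4497, the average effect 42 to 4359 and 18 to 4779, with 0 to 3559 and 3 to 4268 changing less, and the lists called were 34 to 46. Each highest value came without hypoxia 1. The lowest came without hypoxia 2 (2853, 3487), hypoxia 3 (2103, 3133), TEPA 3 (34) or TEPA+hypoxia 2 (42, 18, 3). The counts of 0 for TEPA+hypoxia against TEPA came without TEPA 2, and for genes falling also without TEPA 1, TEPA+hypoxia 2 or TEPA+hypoxia 3. Those of the interaction came without control 1, control 2, hypoxia 3, TEPA 2 or TEPA+hypoxia 3, and that of genes rising less without hypoxia 3, TEPA 1 or TEPA+hypoxia 3. For TEPA against control 0 genes were called by edgeR in every fit without 1 library except that without hypoxia 1 (289 at an unadjusted p under 0.05 with all 12 libraries, 1 and 5 called by DESeq2).

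In the simulation with the spread of all 12 libraries, 4.48% of changed genes at a fold of 1.5 were found for TEPA against control and 2.99% for the interaction. With the spread of the libraries without hypoxia 2 and 3 these were 70.2% and 40.3%. All 12 libraries were simulated in both cases, so neither value applies to the fit without hypoxia 2 and 3. Every library of a gene was drawn with the same spread, so the values do not cover a group that spreads more than the others.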

Other observations

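The genes in this part were chosen after their values were seen, as was the fit without hypoxia 2 and 3, and no explanation for them was tested. Tests of genes in the 2-group fits were also chosen only after the results were seen.

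Some mitochondrial tRNA genes were lower in TEPA+hypoxia than in TEPA. In the fit of those 6 libraries TRNL1 (leucine) changed by -0.97 ± 0.11 (SE, adjusted p = 0.00128), from 29.3 CPM in TEPA to 14.8 CPM, and it stood at 30.5 CPM in control and 13.2 CPM in hypoxia 1. TRNV (valine) changed by -3.01 ± 0.34 (adjusted p = 0.00129), from 4.78 to 0.589 CPM, with 3.91 CPM in control and 0.647 CPM in hypoxia 1. TRNT was at -3.09 ± 0.29, TRND at -2.49 ± 0.34, TRNF at -2.89 ± 0.41 and TRNI at -1.41 ± 0.29, all called. Not called were TRNM (-1.07, adjusted p = 0.0618), TRNE (-1.205, adjusted p = 0.13), TRNQ (-0.455, adjusted p = 0.279) and TRNC (-0.29, adjusted p = 0.653). Nor were TRNY (-0.44, adjusted p = 0.567), TRNP (-0.15, adjusted p = 0.823) and TRNS1, which was at 1.245 (0.533 and 1.21 CPM, adjusted p = 0.0805). Hypoxia without TEPA showed no clear fall of TRNT (2.41 CPM in control; 1.23, 3.01 and 2.05 in hypoxia 1, 2 and 3) or TRNI (1.22; 1.16, 1.03 and 0.0891). Poly(A) selection and short length make counts of tRNA genes hard to read as levels.

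RSRP1 rose at low oxygen with and without TEPA, by 1.20 ± 0.11 and 0.83 ± 0.11, and without hypoxia 2 and 3 by 1.21 and 1.02 (adjusted p = 1.43e-05 and adjusted p = 0.00261). CLK1 rose by 1.35 ± 0.16 and 0.44 ± 0.16, the second of which was not called without hypoxia 2 and 3 (0.69, adjusted p = 0.0655). The long noncoding RNA NEAT1 and the antiproliferative gene BTG2 were not called for TEPA+hypoxia against TEPA with all 12 libraries, and were called without hypoxia 2 and 3 and in the fit of 2 groups (0.68 and 0.71 without them, adjusted p = 0.00234 and adjusted p = 8.77e-04), as was RBM3, a cold-inducible RNA-binding protein gene (-0.48, adjusted p = 0.00200).

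CYP1A1 fell at low oxygen in both settings, by -1.99 ± 0.21 without and -1.55 ± 0.20 with TEPA. TRIM16, its transcribed pseudogene TRIM16L and ABHD4 were lower with TEPA at low oxygen, by -0.64 ± 0.10, -0.74 ± 0.12 and -0.62 ± 0.12, and were called without hypoxia 2 and 3 too. At normal oxygen they were at -0.60 ± 0.10, -0.67 ± 0.12 and -0.60 ± 0.12 (adjusted p = 0.854, 0.854 and 0.914), and with only the 6 libraries compared they were called (adjusted p = 0.0189, 0.0189 and 0.0352). In that fit KRT15, a keratin gene, was higher (0.63 ± 0.08, adjusted p = 0.0137).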
